A study of Drosophila melanogaster with 4 samples.

How the data were processed

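The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) for histone H3 trimethylated at lysine 27 (H3K27me3) in whole larvae of the third instar of Drosophila melanogaster. The flies were the wild-type Oregon-R strain. Per the labels, the antibody was a mouse monoclonal from Abcam, and chromatin was cross-linked with formaldehyde and sheared by sonication. There were 4 libraries: 2 of immunoprecipitated DNA and 2 of input DNA, the sheared chromatin before precipitation. The replicate numbers come from the sample titles. The labels do not say whether replicates came from separate larval collections, so the spread between them may be partly technical.

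The values used were 3 deposited lists of regions of significant enrichment, called clusters here: 1 for each ChIP replicate and 1 for the whole series, called the combined list. Per the file headers, coordinates are on FlyBase release 5 of the genome, and the lengths of the chromosome arms in those headers were used as denominators. Reads were handled with Bowtie version 0.12.7, per the submitters' processing notes. The cluster caller, its threshold, the use of the input libraries, and the way the combined list was made are not given in the sources used here. Each cluster carries a deposited score in the standard score column of the file format. Its unit and scale are not given in the sources used here, so it was used only to rank and filter clusters inside a list, and scores of different lists were not compared as levels. Input libraries had no list in the material analysed here and enter no comparison. The number of reads behind each list is unknown, so differences in the number or width of clusters cannot be separated from differences in depth.

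Cluster overlap was measured in base pairs as the length covered in both lists over the length covered in either (the Jaccard index). The overlap was compared with 1000 circular shifts of the replicate 2 clusters along each chromosome, in a one-sided permutation test. The smallest p these shifts can give is 0.001. A cluster was counted as found in another list when at least 1 bp was shared. Shares of clusters carry 95% Wilson intervals, which treat clusters as independent and cover counting error only. The error of the overlap came from 10000 bootstrap resamples of 1 Mb blocks of the arms. Arm coverage is given as the mean and SD of the 2 replicates. Differences between the 5 large arms were tested by permuting full 1 Mb bins among arms 100000 times, a test added after the lists had been examined. The overlap computation was tested on simulated data: for small lists of 40 intervals each, the interval arithmetic disagreed with a base-by-base count in 0 of 50 simulations. Unrelated lists were then made by shifting the replicate 2 list, with 1819 clusters, against the 2510 clusters of replicate 1. Of 400 such pairs, 26 had a p of 0.05 or less, and 98 of 100 pairs that shared a planted 10% of clusters did. The unrelated lists came from the same kind of shift that the test uses, so the first rate was fixed in advance. It checks the computation only, and does not show that shifts give a fair chance level for real lists. These simulations used fewer shifts per test than the 1000 above. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

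Named clusters follow a rule set before the data were examined: the 10 widest and the 10 highest-scoring clusters of the combined list, by coordinates. Clusters named for the highest score among those of 5 kb or more, and those at arm ends, were chosen after their values were seen. A planned measurement of gene lists was not made. The gene table at hand belongs to release 6 of the genome, and on 5 of the 6 arms it places a gene beyond the arm length in the headers, so genes were not placed on the clusters. Alternatives set beforehand were a score filter at the median of each list, minimum widths of 1 and 5 kb, merging of clusters closer than 5 kb, an overlap of at least 50%, restriction to the 6 arms, random placement in place of shifts, and each replicate alone. Minimum widths of 10 and 20 kb were added later.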

Results

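H3K27me3, the histone mark left by Polycomb group proteins on silenced developmental genes, was mapped in wild-type larvae of the third instar by ChIP-seq. The replicate 1 list held 2510 clusters that covered 12.7 Mb, and the replicate 2 list held 1819 clusters that covered 15.1 Mb. The combined list held 4966 clusters and 21.0 Mb. It is not independent of the replicate lists, since the series has no other ChIP libraries. Coordinates are those of FlyBase release 5. Read depth behind the lists is unknown, and the input libraries were not analysed here.

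The mark lay mainly in a small number of broad regions. In replicate 1, 369 clusters of 5 kb or more made up 14.7% of clusters and 67.2% of the covered sequence. In replicate 2, 426 such clusters made up 23.4% of clusters and 80.0% of the covered sequence. The combined list had 553 of them, 11.1% of clusters with 63.7% of the sequence. Median cluster width was 1798 bp in replicate 1, 2146 bp in replicate 2 and 1588.5 bp in the combined list. Clusters of 50 kb or more numbered 43, 67 and 68 in these lists.

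The widest cluster of the combined list lay on arm 3R from 2648461 to 2890077 and spanned 241.6 kb. Replicate 1 covered 98.8% of it and replicate 2 covered 100%. The next widest, also on 3R, ran from 12587224 to 12810521 over 223.3 kb, with 98.1% covered in replicate 1. Arm 3R carries both homeotic gene complexes, classical Polycomb targets; whether these clusters cover them was not determined, since no gene annotation of this release was used here. Both regions adjoined another wide cluster across a gap of a few kilobases. Left of the second region, the gap ran from 12583116 to 12587279 in replicate 1 and from 12583129 to 12587229 in replicate 2.

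The other wide regions lay on 2L, 3L, 3R and X. On 2L they were 5349966 to 5518820 (168.9 kb), 11316688 to 11484907 (168.2 kb) and 15287729 to 15447003 (159.3 kb). On 3L they were 20541406 to 20704817 (163.4 kb) and 12565481 to 12725501 (160.0 kb). On X they were 4264919 to 4427987 (163.1 kb) and 7394722 to 7550846 (156.1 kb). The tenth was on 3R from 6262852 to 6407595 (144.7 kb). Replicate 2 covered between 98.7% and 100% of each of these 10 regions, and replicate 1 between 68.1% and 99.3%. The lowest replicate 1 values were 68.1% at the 163.4 kb region of 3L and 74.1% at the 159.3 kb region of 2L, each split into 22 replicate 1 clusters.

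**Figure D1:**
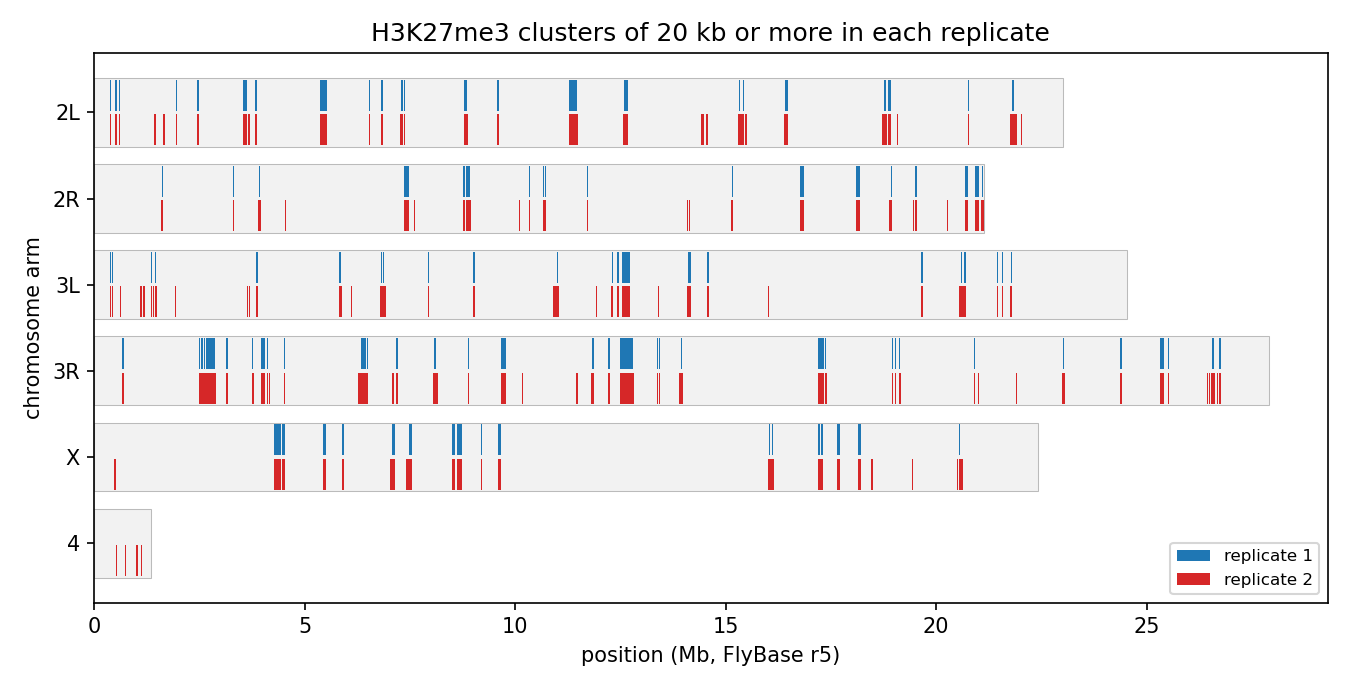
Clusters of 20 kb or more in replicate 1 (blue) and replicate 2 (red) along the 6 arms, with position in Mb (FlyBase r5) on the horizontal axis. There are 135 such clusters in replicate 1 and 166 in replicate 2, and chromosome 4 has 4 of them, all in replicate 2.

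All 5 large arms carried the mark. Clusters covered 13.3% ± 1.04 of 3R (SD, n = 2), 12.5% ± 1.64 of 2L, 10.6% ± 1.52 of 2R, 10.5% ± 0.991 of X and 10.1% ± 1.55 of 3L. Across 117 bins of 1 Mb, no difference between the large arms was detected (permutation test, p = 0.557). Bins ranged from 0.232% at the centromere-proximal start of 2R to 42.8% on 3R between 12 and 13 Mb. The 3R bin between 2 and 3 Mb followed with 39.6% in replicate 1 and 41.7% in replicate 2, and the X bin between 7 and 8 Mb had 32.0% and 39.7%. At the other end, the X bin between 11 and 12 Mb had 0.438% and 0.678%. The small chromosome 4 had 12.3% ± 4.47 covered, from 9.12% in replicate 1 and 15.4% in replicate 2. The assembled heterochromatic sequences had 0.444% ± 0.200 and unplaced sequence U 0.305% ± 0.0433. The combined list covered 1.79% and 1.06% of them. How much of these sequences, or of the start of 2R, reads can be placed on was not measured. The low shares therefore do not show that the mark is absent there.

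**Figure D2:**
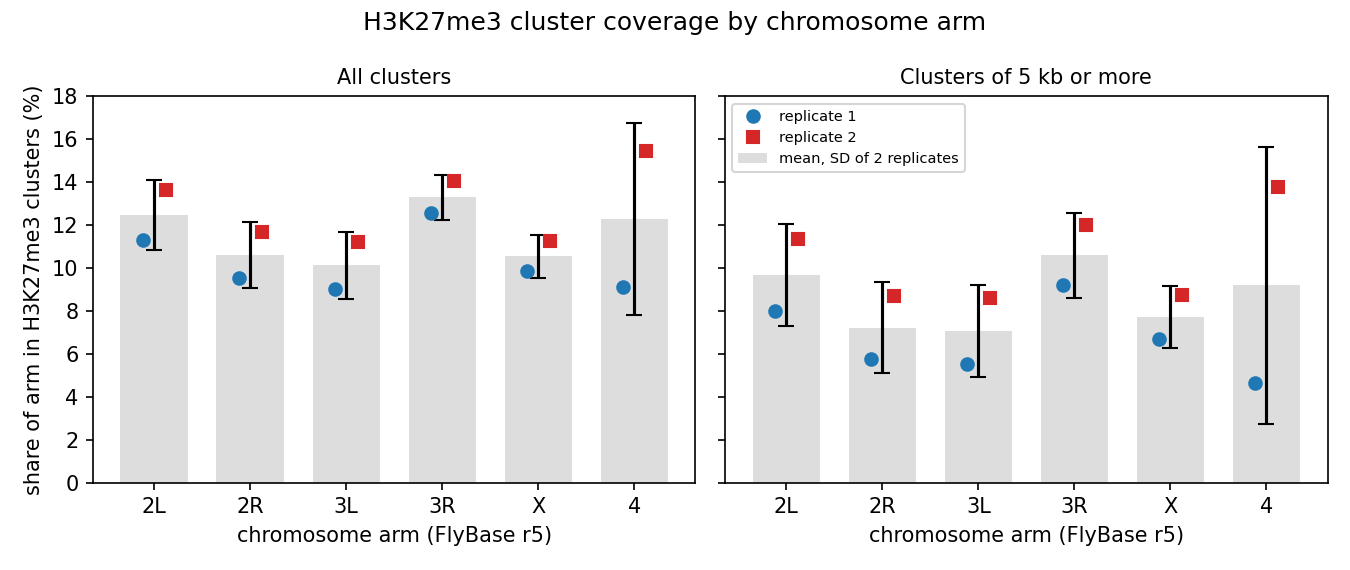
Share of each arm (percent, vertical axis) in all clusters (left) and in clusters of 5 kb or more (right), with grey bars for the mean, error bars for the SD of 2 replicates, and points for each replicate. Chromosome 4 has the widest spread, 9.12% against 15.4% for all clusters.

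The replicates marked largely the same sequence. They shared 11.0 Mb, a Jaccard index of 65.5%, against a mean of 6.06% and a highest value of 18.1% under circular shifts (one-sided permutation test, p = 0.001, the smallest possible). On the arms the index was 65.9%, with a block bootstrap interval of 62.0% to 69.4%. It was 70.9% on 3R, 67.9% on 2L, 67.4% on X, 61.1% on 3L, 59.7% on 2R and 58.9% on chromosome 4. Replicate 2 held 86.5% of the replicate 1 sequence, and replicate 1 held 72.9% of the replicate 2 sequence. Over the 124 bins of the arms, covered length in the replicates had a Spearman correlation of 0.956, across bins that are not independent samples.

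Broad clusters were found again and narrow ones often were not. All 369 replicate 1 clusters of 5 kb or more overlapped replicate 2, and 403 of 426 in replicate 2 overlapped replicate 1 (94.6%, Wilson interval 92.0% to 96.4%). A 1 bp overlap is easier to reach for wide clusters: shifts gave 18.7% and 19.9% at 5 to 10 kb, rising to 47.9% and 66.0% at 50 kb or more. By base pairs, replicate 2 held 99.2% of replicate 1 clusters of 5 to 10 kb, and replicate 1 held 50.0% of replicate 2 clusters of that width, 67.1% at 10 to 20 kb and 92.4% at 50 kb or more. Of replicate 1 clusters of 1 to 2 kb, 43.5% were found in replicate 2 (41.0% to 46.0%), against 14.1% under shifts. In the reverse direction the share was 24.5% (21.6% to 27.7%) against 12.7%. At 2 to 5 kb the shares were 85.0% for replicate 1 clusters and 55.2% for replicate 2 clusters. For clusters of all widths they were 62.5% and 51.2%.

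**Figure D3:**
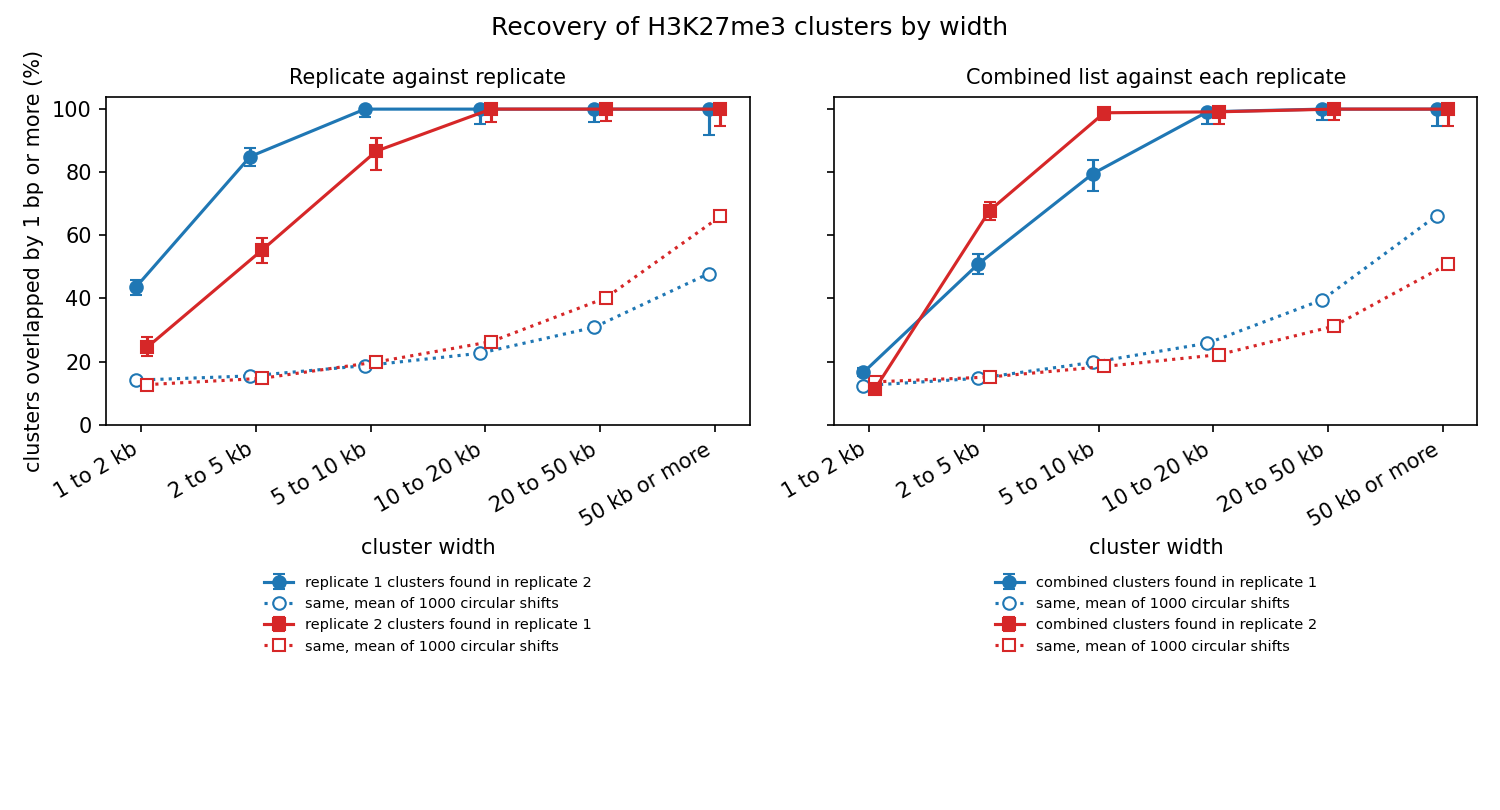
Share of clusters overlapped by another list (percent, vertical axis) by cluster width, for replicate against replicate (left) and the combined list against each replicate (right), with 95% Wilson intervals; dotted lines with open symbols give the mean of 1000 circular shifts. Recovery is 100% from 10 kb upward between replicates, and combined clusters of 1 to 2 kb lie near the dotted lines. For these narrow clusters the dotted lines are too high, since shifted clusters can land where broad combined clusters lie.

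Edges were compared in 93 pairs of clusters of 20 kb or more that covered each other by at least 50%, out of 135 such clusters in replicate 1 and 166 in replicate 2, a choice that favours matching edges. In these pairs 87 of 186 edges (46.8%) lay within 500 bp of each other, and the median distance was 572.5 bp, with an upper quartile of 3916 bp. Replicate 2 reached further out at 179 of 186 edges (96.2%). A replicate 2 cluster of 20 kb or more overlapped 3.84 replicate 1 clusters on average. A replicate 1 cluster of that width overlapped 1.01 of replicate 2. These edge and fragment counts were chosen after the lists had been examined.

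The combined list contained nearly all of both replicates and many narrow clusters besides. It belongs to the same series, so its overlap with the replicate lists is not independent support for either. It held 97.0% of the replicate 1 sequence and 99.0% of the replicate 2 sequence. Of its clusters, 844 (17.0%, 16.0% to 18.1%) overlapped both replicate lists, and these made up 67.3% of its sequence. A further 733 overlapped replicate 1 alone and 775 replicate 2 alone. The other 2614 (52.6%, 51.2% to 54.0%) overlapped neither, with a median width of 1240 bp and 17.0% of the sequence. The lists differ in their lower width limit: the narrowest cluster was 1001 bp in the combined list and 1301 bp in each replicate list. Of 1692 combined clusters narrower than 1301 bp, 1493 (88.2%) overlapped neither, against 1121 (34.2%) of the 3274 wider ones. The share in neither is therefore not a plain measure of missing replicate support. At 5 kb or more, 495 of 553 were in both replicate lists and 0 in neither. At 1 to 2 kb, 16.6% were found in replicate 1, where shifts gave 10.9% to 14.0%, and 11.3% in replicate 2, where shifts gave 11.9% to 15.4%. These shift levels are too high for narrow clusters. Combined clusters of 5 kb or more covered 13.4 Mb, of which 95.7% lay in replicate 2 and 79.2% in replicate 1. Narrow combined clusters cannot lie there, but shifted ones can, so the comparison does not show recovery at or below chance.

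In both replicates the top-scoring cluster was near the distal end of 2L, from 5061 to 13440 in replicate 1 and from 5016 to 14228 in replicate 2. In replicate 1 ranks 3 and 4 were narrow clusters of 1409 bp on 3L and 1589 bp on U, with the same score and no overlap with replicate 2. The first 5 ranks of replicate 2 were 9.21 to 43.0 kb wide and at least 77.5% covered in replicate 1. In both replicate lists every cluster was at least 1301 bp wide. The 10 highest-scoring combined clusters were all narrow, 1001 to 2003 bp, and none overlapped a replicate cluster. The first was on 3R from 27903467 to 27904888, 0.165 kb from the distal end of the arm. Of the 10, 4 lay on U, 2 on heterochromatic sequence of 2R, and 4 on the arms, the first included. Among combined clusters of 5 kb or more, the highest scores were at 2L from 5024 to 14325, 2R from 5859828 to 5877141 and 2R from 10321768 to 10355846. Replicate 1 covered between 77.6% and 99.7% of the first 10 such clusters, and replicate 2 between 99.0% and 100%. Scores of overlapping clusters in the replicates had a Spearman correlation of 0.487 over 1619 pairs, and of 0.853 over the 555 pairs that covered each other by at least 50%. Cluster widths correlated at 0.465 and 0.859 in the same pairs. Score also rose with width inside the replicate lists, with a Spearman correlation of 0.585 in replicate 1 and 0.733 in replicate 2. In the combined list this correlation was weaker, at 0.243. Agreement in score between the replicates was therefore not separated from agreement in width.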

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

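The minimum widths of 10 and 20 kb were chosen after the lists had been examined, and the other settings before. The overlap of the replicates stayed above its chance level in all settings tried, from 65.5% to 70.3%, each with the smallest p the shifts or random placements can give; the minimum of 1 kb removes no cluster and tests nothing. Requiring 50% of a cluster to be covered lowered the share found again to 60.0% for replicate 1 and 39.3% for replicate 2. For the combined list it gave 10.7% in both, 34.1% in 1 and 55.2% in neither. Clusters at or above the median score gave 18.4%, 25.2% and 56.4%. With a single replicate list, between 31.8% and 32.6% of combined clusters were found, against 47.4% with either, a drop fixed by using fewer lists. Score correlation was 0.853 with reciprocal 50% overlap, a rule that also pairs clusters of like width. The cause was not tested. Clusters at or above the median score covered 10.7% of 2L, 8.45% of 2R, 8.20% of 3L, 11.6% of 3R and 9.86% of the 6 arms. Clusters of 5 kb or more covered 9.67% of 2L, 7.23% of 2R, 7.07% of 3L, 10.6% of 3R, 7.72% of X and 8.56% of the 6 arms. Both filters only remove sequence. Merging clusters closer than 5 kb left 1428, 919 and 2503 clusters in replicate 1, replicate 2 and the combined list, and raised the replicate 2 median width to 3621 bp. Arm coverage from 1 replicate alone is within 1 SD of the mean of both by construction and says nothing about stability. The gene list alternatives were not run. No paired analysis was possible because the input libraries have no list here and no test compares the groups. Depth is unknown, so it was not tested as a source of the differing cluster numbers.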

Other observations

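The tests of score ties, unplaced sequence, broken-up domains, short gaps, arm ends and median score and width on chromosome 4 were chosen after the result was seen. The matched draws and the test of regional variation for chromosome 4 were chosen before. The design has 1 condition, so no biological explanation was tested.

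The distal end of 2R was densely marked. Of its last 100 kb, 53.8% was covered in replicate 1 and 79.2% in replicate 2, against 8.38% and 9.21% at the distal end of 2L, 5.71% and 7.26% on 3R, 1.37% and 0% on 3L, and 0% in both on X. The hypothesis that distal ends carry more of the mark than other windows could not be decided: the 5 ends averaged 16.5%, against 11.4% for random windows (one-sided permutation test, p = 0.270), and the 2R end supplies most of that mean. Clusters near the 2L and 3R ends were high-scoring, ranking 1 and 13 by score in replicate 1 and 1 and 22 in replicate 2.

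Wide neighbouring clusters were in places separated by short gaps. Replicate 2 had 21 gaps under 10 kb between clusters of 20 kb or more, and all 21 were under 10% filled in replicate 1, against 0.757 on average and at most 6 in draws of windows inside wide clusters (one-sided permutation test, p = 1e-04, the smallest possible). This test cannot decide whether the replicates keep the same gaps, since replicate 1 lies mostly inside replicate 2 and would leave such gaps open anyway. In the other direction, 5 of 17 replicate 1 gaps were under 10% filled in replicate 2, against 0.0025 on average and at most 1 in the draws (one-sided permutation test, p = 1e-04, the smallest possible). This test decides nothing either, since wide replicate 1 clusters are 99.9% covered by replicate 2, so the windows drawn inside them are almost never open. Of the other 12 gaps, 10 were filled completely. The 5 open gaps included 2L 7344127 to 7349518, 3L 403620 to 408836 and 3R 17346056 to 17354189, named after their values were seen.

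The highest scores of the combined list lay in narrow clusters absent from both replicate lists, which hold no cluster under 1301 bp. Among clusters under 5 kb with a score of 2 or more, 72.2% (26 of 36) had the score of another cluster to 9 decimals, against 42.4% of those with lower scores and 0 of 64 broad clusters with a score of 2 or more (Fisher's exact test against the broad clusters, p = 3.63e-16; against the lower-scoring narrow clusters, p = 0.000510). At 5 decimals, 2 of the 64 were tied as well. Tied clusters are not independent: the 36 held 17 distinct scores, and 7 of them shared the commonest score. Fisher's test counts each cluster separately, so its p-values for ties overstate the evidence. The ties could come from scores set by few reads if the score is a ratio of counts, since few ratios are then possible. The scale of the score is not given in the sources used here, and the read counts were not analysed. Of the 36 clusters, 63.9% lay off the 6 arms, on unplaced or heterochromatic sequence (Wilson interval 47.6% to 77.5%), against 3.43% of the lower-scoring narrow clusters (Fisher's exact test, p = 1.52e-24) and 0 of the 64 broad ones. This test also counts each cluster separately. It was chosen after the highest-scoring clusters had been seen, and those clusters are among the 36. Its p-value therefore overstates the evidence as well. Such sequence may contribute, and the other 13 of the 36 lay on the arms.

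Replicate 2 covered more sequence in fewer clusters than replicate 1. The fewer clusters could come from domains broken up in replicate 1. Of the difference of 691 clusters, 92.0% (block bootstrap interval 74.9% to 115%) lay among clusters overlapping the other replicate, 1568 in replicate 1 and 932 in replicate 2. Merging clusters closer than 5 kb took replicate 1 from 2510 to 1428 clusters and replicate 2 from 1819 to 919. It thinned both lists and left most of the difference, so gaps under 5 kb account for only a minor part of it. Sequence between the pieces of such domains was not the main part of the added sequence: of the net 2.37 Mb, 34.9% (28.1% to 42.6%) lay between clusters inside 1 cluster of the other replicate. Another 52.4% (46.0% to 61.2%) lay beyond the outermost such cluster. Domains that lost their outer pieces in replicate 1 would count there, so broken-up domains are not excluded as the main source. Clusters with no overlap, 942 in replicate 1 with 1.51 Mb and 887 in replicate 2 with 1.81 Mb, gave the other 12.8%. A difference in depth or in enrichment between the libraries stays open as untested.

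Among the 6 arms, chromosome 4 had the largest ratio of covered length between the replicates, 1.69 against 1.12 to 1.24 on the large arms; the heterochromatic sequences had 1.94. Its Jaccard index of 58.9% was close to the 59.7% of 2R. Replicate 1 covered 59.0% of its replicate 2 sequence, below the 65.4% to 81.5% of draws matched on score and width, but the draws treat clusters as independent, and the central 95% of whole windows of this length ranged from 32.5% to 94.5%, so they decide nothing about weaker or narrower clusters. The median width of its replicate 2 clusters, 6453 bp, was at or above that of 98.0% of windows, so those clusters were not narrow. Broad replicate 2 clusters are part of the pattern itself: clusters of 5 kb or more covered 13.8% of chromosome 4 in replicate 2 and 4.63% in replicate 1. Replicate 1 widths were not compared with windows, so narrower clusters in replicate 1 were not tested. The median score, 0.849 against a median of 0.657, was at or above that of 96.4% of windows; it was not low, but it lies within the central 95% of windows and excludes nothing. Variation between regions of this size may account for this: 13.9% of 801 windows had as low a share, and 6.37% as high a ratio. The 801 windows are those of 1124 with 100 kb or more covered in replicate 2. They are 1.35 Mb long, start every 100 kb and overlap heavily. All shares of windows given here are therefore rough and do not count separate regions.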
